A study of Saccharomyces cerevisiae with 60 samples.

How the data were processed

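Budding yeast of the W303 background, grown in rich glucose medium with adenine, was measured as poly(A) RNA with a Lexogen SENSE mRNA-Seq kit and 50 bp single reads on an Illumina HiSeq, per the labels. Each of 60 libraries holds 1 sample, with 3 libraries per group. Rapamycin or DMSO was given for 45 min at 25 °C before heat.

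The authors deposited raw read counts for 7126 features per library. Their processing notes name featureCounts 2.0.0, bcl2fastq 1.8.4 and build R64, and the column headers name contextmap and trimming. The settings, and whether counting used the strand, are not given in the sources used here. The authors also deposited a table of log2 fold changes and p-values (false discovery rates) for the 16 heat responses, made with DESeq2 1.28.1 or DESeq, and it was used here for comparison only. Of the features, 6048 matched the R64 reference by locus tag, and 0.459% of counts lay on the others. For 5710 of 5721 single-exon features both ends equalled the reference, and positions come from it.

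Genes were filtered with filterByExpr, which kept 6070 and removed 1056. All 60 libraries were fitted together in R 4.3.3 with edgeR 4.0.16, with 1 mean per group, TMM scaling and the quasi-likelihood F test (two-sided), and the common biological coefficient of variation was 0.276. Adjustment was by Benjamini-Hochberg over all tested genes in each of 40 comparisons. A gene is called up or down, higher or lower, at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The comparisons were 4 at 25 °C, 16 of heat against 25 °C in the same strain state, 12 of a heat response minus that of wild type, 4 of non-additivity (the double-loss difference minus the sum of both single-loss differences) and 4 within wild type between temperatures or times. Log2 fold changes carry standard errors, and CPM values carry standard deviations.

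Lists of genes were fixed from textbook knowledge before the data were examined, as were the comparisons, thresholds, naming rule and alternatives except where stated. None was chosen on these samples. The 27 lists with enough members were tested in each comparison with camera in limma 3.58.1 (two-sided, preset correlation of 0.01, adjusted over the lists), and again with an estimated correlation. A list of mitochondrial genome genes was left out since 1 of its 16 members passed the filter. Calls within a list are given over all genes and adjusted over the list alone.

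Named genes follow a rule. They are HSF1, MSN2 and MSN4, 30 stress, chaperone and ribosome genes chosen beforehand, the 8 largest rises and 8 largest falls per comparison among called genes with a symbol and an average log2 CPM of at least 3, and up to 4 called members of a described list. For the largest changes between 2 groups, all 3 libraries of 1 group also lay above all 3 of the other, which chance gives for 10% of genes. The tables made under the rule hold 3977 pairs of a gene and a comparison, and the 255 printed were picked from these with their values in view. Some genes named by the rule are not reported here.

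Floors for 0 counts use 3 counts per library, or 0.296 to 0.78 CPM. On simulated data of the same design, 84 of 100 genes changed by 1.5 on the log2 scale were recovered in a heat response, 63 in a difference and 81 at 25 °C, and 100, 98 and 99 at a change of 3, with 8, 10 and 6 false calls among 6056 genes. No pair of replicates was a duplicate, with a chi-square per degree of freedom between 9.25 and 235.21.

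The names of the deposited count tables divide the libraries into 6 sets of 10, with 3 sets in each MSN background. The set was not in the fit and was added as a term in an alternative, which 2 comparisons at 25 °C do not allow. Other alternatives were edgeR with DESeq2's size factors (RLE), library totals alone, no filter, DESeq2 1.42.0 on all libraries, the compared libraries alone, the replicate number as a block, an adjusted p under 0.01, and leaving out each library in turn. A fit without the 5 libraries farthest from their groups was chosen after seeing the data. Library totals moved the median of all genes by -0.56 to 1.01 (log2), so log2 fold changes are relative to the TMM scale. Upstream sites were read from 500 bp windows with Biopython 1.88, and Fisher's and permutation tests were run with scipy 1.17.1 in Python 3.11.15. No library was left out.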

Results

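Poly(A) RNA of budding yeast was sequenced in 60 libraries, 3 in each of 20 groups made of 4 strain states and 5 conditions. All strains carried an anchor-away tag on Hsf1, the essential transcription factor of the heat shock response. In anchor-away, rapamycin ties a tagged nuclear protein to a protein that leaves the nucleus. Cells given the solvent DMSO are called wild type here, and cells given rapamycin before heat are called Hsf1-depleted. A further strain lacked MSN2 and MSN4, a pair of related activators of the general stress response, and was given DMSO (MSN-deleted) or rapamycin (double loss). Each state was sampled at 25 °C and after 10 or 30 min at 37 °C or 42 °C. The deposited counts summed to between 3848210 and 10142858 per library (median 5938357), and 5839 to 6406 genes had a count. A gene with 0 counts in a library is thus below 0.296 to 0.78 CPM (counts scaled to a common library total), a limit that covers counting error only. The labels do not call replicates separate cultures, so p-values measure the spread between these samples. HSP12, KRI1, DBP2, MF(ALPHA)2, RPL9A, PUF6, RPS19A, GPM2 and DDR2 had a mean below 0.78 CPM in at least 1 group they are compared in below, so those fold changes rest on few counts.

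The targeted genes were read in every library. MSN2 (YMR037C, chromosome XIII, 344403 to 346517, build R64) and MSN4 (YKL062W, chromosome XI, 323228 to 325120) had 99.75 to 272.61 and 64.48 to 458.13 CPM in the 30 libraries of the intact strain. In the 30 libraries of the deleted strain, MSN2 reached at most 0.38 CPM and MSN4 at most 1.71 CPM, each with a count in 3 libraries. HSF1 (YGL073W, chromosome VII, 368753 to 371254) had 67.32 to 474.5 CPM in the intact and 64.05 to 496.1 CPM in the deleted strain. Anchor-away moves the protein and not its mRNA, so the HSF1 counts are no check of the depletion. In wild type, HSF1 mRNA rose after 10 min at 37 °C (log2 fold change 1.78 ± 0.21) and 30 min at 42 °C (2.28 ± 0.22), and HSF1 overlaps a gene on the opposite strand at each end.

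At 25 °C, Hsf1-depleted cells were compared with wild type to find what Hsf1 sustains without heat. The mRNAs of some chaperones fell. The log2 fold changes were SSA2 -3.99 ± 0.26 and SSA1 -3.03 ± 0.31 for the Hsp70 chaperones and HSC82 -3.97 ± 0.38 and HSP82 -3.73 ± 0.37 for the Hsp90 chaperones (standard errors here and below, n = 3 libraries per group, edgeR adjusted p at most 1.05e-09). Reads shared within these pairs of near-identical genes leave their split uncertain, and SSA1 overlaps an opposite-strand feature. The transcriptional coactivator gene MBF1 (-3.18 ± 0.43), the Hsp70 partner SIS1 (-2.84 ± 0.25), the Hsp70 to Hsp90 adaptor STI1 (-2.16 ± 0.26) and the protein-sorting factor CUR1 (-1.80 ± 0.35) fell too. In the list of 18 core Hsf1 chaperone targets, 12 of 18 fell (16 adjusted over the list alone, median -1.76, adjusted p = 6.20e-110). edgeR called 0 genes up and 12 down (0 and 16 with the library set as a term), and the 12 were all members of that list. The call of CUR1 ended in a fit on these libraries alone and without Hsf1-depleted at 25 °C replicate 2 (-1.52). Against the 0 rises, 414 genes had an unadjusted p under 0.05 and DESeq2 called 0 up and 16 down.

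In MSN-deleted cells at 25 °C, the question was the same for Msn2 and Msn4. Besides the deleted genes, a hexokinase (HXK1 -3.81 ± 0.48, which overlaps a same-strand feature), glycogen phosphorylase (GPH1 -3.51 ± 0.64) and the ceramidase YPC1 (-1.96 ± 0.34) fell, and the secreted acid phosphatase PHO5 rose (1.40 ± 0.32, edgeR adjusted p at most 0.0437). Among 36 general stress genes, 2 of 36 fell (8 adjusted over the list alone, median -0.57, adjusted p = 1.99e-13, adjusted p = 0.18 with an estimated correlation). edgeR called 1 gene up and 6 down, DESeq2 2 and 12, and DESeq2's size factors in edgeR left 0 and 6. The call of GPH1 ended without wild type at 25 °C replicate 3 (-2.81). The call of PHO5 ended without MSN-deleted at 25 °C replicates 2 (1.38) and 3 (1.01) or wild type at 25 °C replicates 1 (1.30) and 3 (1.12), with both other scalings, with no filter and on these libraries alone. In the double loss against wild type, the small membrane stress protein HSP12 (-5.398 ± 1.20), HXK1 (-4.33 ± 0.50), GPH1 (-3.54 ± 0.65) and the chaperones SSA2 -4.35 ± 0.27 and HSC82 -3.56 ± 0.37 fell, while SNO1 of vitamin B6 metabolism (1.81 ± 0.41), PHO5 (1.54 ± 0.32) and ADE17 of purine synthesis (1.26 ± 0.30) rose. In the core list 12 of 18 fell (14 adjusted over the list alone, median -1.90, adjusted p = 5.72e-121), out of 3 genes up and 27 down. A fit on these libraries alone called 0 up and 12 down, and one without 5 libraries that stood apart, chosen after seeing the data, called 13 and 37. The fit on these libraries alone ended the calls of GPH1, PHO5, ADE17 and SNO1, the fit without those that stood apart the calls of HSP12 and SNO1, and library totals that of SNO1. Leaving out 1 library ended the call of SNO1 without double loss at 25 °C replicates 2 (1.73) and 3 (1.48) or wild type at 25 °C replicates 1 (1.85), 2 (1.61) and 3 (1.82), of ADE17 without double loss at 25 °C replicates 1 (1.22) and 3 (0.98) or wild type at 25 °C replicates 1 (1.30), 2 (1.21) and 3 (1.12), of PHO5 without double loss at 25 °C replicate 3 (0.93) or wild type at 25 °C replicates 1 (1.46) and 3 (1.25) and of HSP12 without double loss at 25 °C replicates 1 (-5.22) and 2 (-4.82) or wild type at 25 °C replicate 3 (-4.17). The library sets, known from table names alone, are nested in the MSN background, so for these comparisons set and deletion cannot be told apart. Against MSN-deleted cells, the double loss had lower SSA2 -4.66 ± 0.27, SIS1 -3.48 ± 0.26 and HSP82 -3.54 ± 0.35, and in the core list 12 of 18 fell (17 adjusted over the list alone, median -2.09, adjusted p = 1.49e-23 with an estimated correlation). edgeR called 0 genes up and 20 down (0 and 23 with the library set as a term), with 80 genes at an unadjusted p under 0.05 and 0 up and 22 down by DESeq2, and a fit on these libraries alone called 0 and 9.

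Wild-type cells after 10 min at 37 °C had a broad response. The small heat shock proteins HSP26 and HSP42, which hold unfolded proteins, rose with log2 fold changes of 9.59 ± 0.75 and 8.58 ± 0.57. The trehalose synthase subunit TSL1 (8.14 ± 0.58), cytosolic catalase CTT1 (7.64 ± 0.54) and the heat-inducible Hsp70 SSA4 (7.26 ± 0.40) rose as well (edgeR adjusted p at most 5.08e-15). NSR1 of pre-rRNA processing (-7.07 ± 0.56, which overlaps an opposite-strand feature), RRP5 of pre-rRNA cleavage (-6.85 ± 0.50) and URA7 of CTP synthesis (-7.43 ± 0.56) fell. By list, 14 of 18 rose (14 adjusted over the list alone, median 3.35, adjusted p = 1.06e-15) among core chaperones, 34 of 36 rose (35 adjusted over the list alone, median 4.97, adjusted p = 2.27e-24) among general stress genes, 17 of 18 rose (17 adjusted over the list alone, median 4.03, adjusted p = 1.12e-17) among trehalose and glycogen genes and 92 of 92 fell (92 adjusted over the list alone, median -4.97, adjusted p = 4.03e-57) among ribosome biogenesis genes. Medians are of log2 fold changes and list p-values are from camera. edgeR called 1274 genes up and 1347 down (1280 and 1430 with the library set as a term). Scaled by library totals alone, 803 up and 1959 down (29.1% up in place of 48.6%).

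After 30 min at 37 °C, genes of the same stress lists were called. HSP26 (6.68 ± 0.67), TSL1 (5.01 ± 0.51) and the glycolytic dehydrogenase TDH1 (7.40 ± 0.54) rose, and the RNA helicase DBP2 (-7.21 ± 0.45) fell. Of core chaperones 10 of 18 rose (10 adjusted over the list alone, median 1.34, adjusted p = 1.53e-07). Among general stress genes 33 of 36 rose (33 adjusted over the list alone, median 3.13, adjusted p = 1.18e-22). Among unfolded protein response genes of the endoplasmic reticulum 11 of 20 rose (11 adjusted over the list alone, median 1.09, adjusted p = 9.95e-06). For ribosomal protein genes, 1 of 136 rose and 62 fell (1 and 66 adjusted over the list alone, median -1.01, adjusted p = 2.36e-09, adjusted p = 0.226 with an estimated correlation). Of histone genes 8 of 10 fell (8 adjusted over the list alone, median -2.33, adjusted p = 3.94e-05). edgeR called 874 genes up and 796 down (905 and 867 with the library set as a term). Between 10 and 30 min at 37 °C, SSA4 (-5.23 ± 0.36), CTT1 (-4.60 ± 0.47) and the Hsp70-interacting BTN2 (-4.02 ± 0.42) fell, and URA7 (4.30 ± 0.56), RRP5 (4.33 ± 0.48) and the fatty acid desaturase OLE1 (3.94 ± 0.33) rose (edgeR adjusted p at most 4.78e-08). Core chaperones (15 of 18 fell (15 adjusted over the list alone, median -1.80, adjusted p = 5.95e-19)), general stress genes (29 of 36 fell (30 adjusted over the list alone, median -2.09, adjusted p = 1.05e-17)) and respiration genes (31 of 44 fell (33 adjusted over the list alone, median -1.54, adjusted p = 4.46e-20)) fell, and ribosome biogenesis genes rose (79 of 92 rose (82 adjusted over the list alone, median 2.62, adjusted p = 4.25e-44)). edgeR called 628 genes up and 514 down (721 and 533 with the library set as a term). Library totals gave 1045 up and 278 down (79% up in place of 55%).

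At 42 °C, 10 min of heat raised HSP26 (10.29 ± 0.77), HSP42 (8.98 ± 0.58), SSA4 (8.35 ± 0.41), the plasma membrane stress protein HSP30 (11.33 ± 0.91) and BTN2 (8.39 ± 0.52) in wild type. The ribosome assembly factors REI1 (-7.01 ± 0.49), NHP2 (-5.60 ± 0.43) and PUF6 (-5.56 ± 0.37) fell (edgeR adjusted p at most 1.15e-14). Among core chaperones 18 of 18 rose (18 adjusted over the list alone, median 4.19, adjusted p = 4.95e-23). Among general stress genes 35 of 36 rose (35 adjusted over the list alone, median 4.73, adjusted p = 2.27e-22). For glucose transporter genes, 9 of 12 rose (9 adjusted over the list alone, median 1.93, adjusted p = 0.00247, adjusted p = 0.0944 with an estimated correlation). edgeR called 1405 genes up and 1104 down (1451 and 1139 with the library set as a term). Library totals gave 1017 up and 1745 down (36.8% up in place of 56%). Against 10 min at 37 °C, HSP30 (4.97 ± 0.69), MNC1 (5.78 ± 0.54), the invasive growth gene DIA1 (5.61 ± 0.39) and the glucose transporter HXT1 (4.61 ± 0.60) were higher, and the mating-type switching regulators ASH1 (-2.75 ± 0.31) and SWI5 (-2.83 ± 0.30) were lower. For core chaperones, 9 of 18 were higher (9 adjusted over the list alone, median 1.001, adjusted p = 0.000187, adjusted p = 0.19 with an estimated correlation). Of ribosome biogenesis genes 58 of 92 were higher (62 adjusted over the list alone, median 1.62, adjusted p = 1.84e-12, adjusted p = 0.353 with an estimated correlation). edgeR called 935 genes higher and 402 lower (1081 and 397 with the library set as a term).

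After 30 min at 42 °C wild type had the most called genes among its 4 heat conditions. HSP26 rose by a log2 fold change of 12.71 ± 0.84, HSP30 by 12.26 ± 0.94, HSP42 by 9.88 ± 0.60 and SSA4 by 9.24 ± 0.43. The ribosomal protein genes RPL3 (-6.65 ± 0.34) and RPS19A (-8.30 ± 0.79) and the ribosome assembly gene PUF6 (-8.54 ± 0.47) fell (edgeR adjusted p at most 5.86e-13). Many ribosomal protein genes come in near-identical pairs, whose split is uncertain. The share of all counts on ribosomal protein and ribosome biogenesis genes was 12.7% ± 1.17 (SD, n = 3) at 25 °C and 0.21% ± 0.0337 after this heat. Among ribosomal protein genes 134 of 136 fell (135 adjusted over the list alone, median -5.71, adjusted p = 2.11e-44). For ribosome biogenesis genes, 92 of 92 fell (92 adjusted over the list alone, median -5.45, adjusted p = 1.29e-33). Of RNA polymerase I and III genes 1 of 22 rose and 21 fell (1 and 21 adjusted over the list alone, median -4.73, adjusted p = 4.64e-07, adjusted p = 0.0747 with an estimated correlation). Of core chaperones 18 of 18 rose (18 adjusted over the list alone, median 3.95, adjusted p = 1.48e-12). As to general stress genes, 36 of 36 rose (36 adjusted over the list alone, median 5.397, adjusted p = 1.19e-15). For trehalose and glycogen genes, 16 of 18 rose (16 adjusted over the list alone, median 3.92, adjusted p = 5.15e-09, adjusted p = 0.0747 with an estimated correlation). Of endoplasmic reticulum genes 14 of 20 rose and 1 fell (14 and 1 adjusted over the list alone, median 2.55, adjusted p = 4.20e-06). edgeR called 1832 genes up and 1789 down (1853 and 1813 with the library set as a term). Library totals gave 1373 up and 2399 down (36.4% up in place of 50.6%).

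The other lists at 42 °C for 30 min in wild type follow. Among amino acid synthesis genes 4 of 53 rose and 39 fell (4 and 40 adjusted over the list alone, median -1.94, adjusted p = 1.91e-08, adjusted p = 0.0828 with an estimated correlation). For ergosterol synthesis genes, 3 of 26 rose and 16 fell (3 and 16 adjusted over the list alone, median -1.43, adjusted p = 0.0109, adjusted p = 0.402 with an estimated correlation). Of chaperonin and prefoldin genes, which fold actin and tubulin, 13 of 14 fell (13 adjusted over the list alone, median -2.42, adjusted p = 0.000316, adjusted p = 0.106 with an estimated correlation). Of G1/S genes 15 of 22 fell (15 adjusted over the list alone, median -1.42, adjusted p = 0.000349), and of G2/M genes 1 of 23 rose and 18 fell (1 and 18 adjusted over the list alone, median -2.08, adjusted p = 2.11e-05). Among ubiquitin and autophagy genes 14 of 25 rose (14 adjusted over the list alone, median 1.42, adjusted p = 0.000316). For oxidative defence genes, 17 of 30 rose and 2 fell (17 and 2 adjusted over the list alone, median 1.62, adjusted p = 0.0108, adjusted p = 0.18 with an estimated correlation). Of nitrogen catabolite repressed genes 12 of 25 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.71, adjusted p = 0.00336, adjusted p = 0.235 with an estimated correlation). For the lists of other cytosolic chaperones (9 of 23 rose and 10 fell (9 and 10 adjusted over the list alone, median -0.27, adjusted p = 0.555), where median and test differ in sign), mitochondrial chaperones (5 of 11 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.86, adjusted p = 0.0665)), the proteasome (1 of 32 fell (1 adjusted over the list alone, median -0.49, adjusted p = 0.496)), glycolysis (9 of 21 rose and 4 fell (9 and 4 adjusted over the list alone, median 0.03, adjusted p = 0.109)), glucose transport (7 of 12 rose and 3 fell (7 and 3 adjusted over the list alone, median 1.39, adjusted p = 0.316)), respiration (10 of 44 rose and 10 fell (10 and 10 adjusted over the list alone, median -0.06, adjusted p = 0.676), where median and test differ in sign), cell wall integrity (12 of 25 rose and 7 fell (12 and 7 adjusted over the list alone, median 0.62, adjusted p = 0.345)), histones (8 of 10 fell (8 adjusted over the list alone, median -1.88, adjusted p = 0.0639)) and iron uptake (7 of 23 rose and 5 fell (7 and 5 adjusted over the list alone, median 0.70, adjusted p = 0.337)), the list test was not passed.

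**Figure D1:**
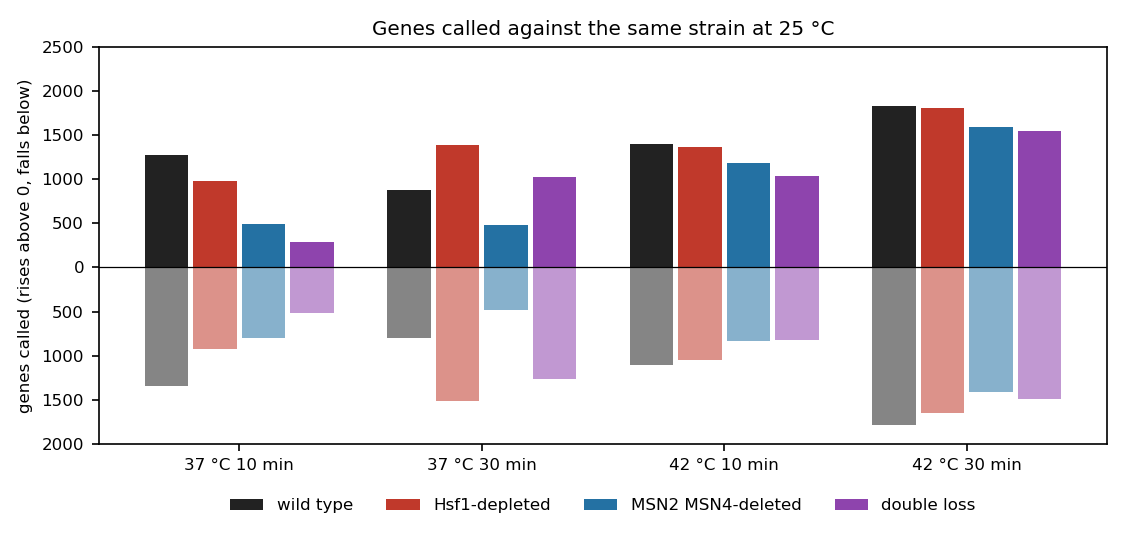
Bars give the number of genes edgeR called up (above 0) or down (below 0) against 25 °C in the same strain state, for 4 strain states and 4 heat conditions on a linear axis from 0. Wild type had 1832 rises and 1789 falls at 42 °C for 30 min, and the double loss had 284 and 519 at 37 °C for 10 min. Bars are TMM-scaled counts, and under library totals the double loss there has 496 rises and 316 falls.

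Between 10 and 30 min at 42 °C, ribosomal protein genes fell further. RPL3 (-6.04 ± 0.33) and ARO4 of aromatic amino acid synthesis (-6.88 ± 0.41) fell. TDH1 (4.06 ± 0.46), the Kar2 nucleotide exchange factor SIL1 (3.25 ± 0.23) and KAR2, the Hsp70 of the endoplasmic reticulum (1.17 ± 0.28), rose (edgeR adjusted p at most 0.000597). Among ribosomal protein genes 128 of 136 fell (128 adjusted over the list alone, median -4.28, adjusted p = 8.58e-87). For endoplasmic reticulum genes, 9 of 20 rose (9 adjusted over the list alone, median 0.91, adjusted p = 5.76e-08). Among core chaperones 1 of 18 fell (1 adjusted over the list alone, median -0.05, adjusted p = 0.842), where median and test differ in sign. edgeR called 638 genes up and 991 down (680 and 1044 with the library set as a term). At 30 min, 42 °C against 37 °C gave higher SSA4 (7.22 ± 0.39), HSP30 (8.83 ± 0.82), the glucose transporter HXT5 (7.48 ± 0.58) and ATG41 of autophagy (7.52 ± 0.72), and lower RPS19A (-7.10 ± 0.79) and RPS0B (-7.04 ± 0.57). For core chaperones, 18 of 18 were higher (18 adjusted over the list alone, median 2.49, adjusted p = 9.58e-13). Of general stress genes 32 of 36 were higher (33 adjusted over the list alone, median 2.27, adjusted p = 3.61e-09, adjusted p = 0.167 with an estimated correlation). Among ribosomal protein genes 130 of 136 were lower (130 adjusted over the list alone, median -4.77, adjusted p = 2.58e-58). edgeR called 1308 genes higher and 1352 lower (1341 and 1378 with the library set as a term). Library totals gave 940 higher and 1879 lower (33.3% higher in place of 49.2%).

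Hsf1-depleted cells heated to 37 °C for 10 min still raised the general stress genes. CTT1 (6.86 ± 0.53), phosphoglucomutase PGM2 (6.76 ± 0.44) and TSL1 (6.16 ± 0.54) rose, as did HSP42 (5.22 ± 0.49) and the disaggregase HSP104 (4.56 ± 0.30), and the J protein YDJ1 fell (-1.86 ± 0.19, edgeR adjusted p at most 4.62e-11). SSA4 was not called (0.67 ± 0.31). For general stress genes, 36 of 36 rose (36 adjusted over the list alone, median 4.62, adjusted p = 2.75e-30). Of core chaperones 10 of 18 rose and 1 fell (10 and 1 adjusted over the list alone, median 1.31, adjusted p = 9.86e-06). edgeR called 980 genes up and 922 down (1010 and 966 with the library set as a term). Against the wild-type response, SSA4 (-6.59 ± 0.47), the zinc finger protein gene ZPR1 (-5.18 ± 0.31), BTN2 (-5.47 ± 0.60) and HSP26 (-5.01 ± 0.80) were lower. VPS62 (5.08 ± 0.54) and the ribosome assembly genes KRI1 (3.88 ± 0.90) and UTP13 (3.01 ± 0.55) were higher (edgeR adjusted p at most 0.00739). Among core chaperones 1 of 18 were higher and 8 lower (1 and 11 adjusted over the list alone, median -1.49, adjusted p = 1.47e-21). Of ribosome biogenesis genes 33 of 92 were higher (62 adjusted over the list alone, median 1.71, adjusted p = 5.85e-28, adjusted p = 0.0826 with an estimated correlation). edgeR called 100 genes higher and 96 lower (308 and 325 with the library set as a term), DESeq2 133 and 339, edgeR with DESeq2's size factors 87 and 167, library totals 191 higher and 40 lower (82.7% higher in place of 51%), the libraries of these groups alone 8 and 27, and a fit without the 5 libraries that stood apart 15 and 39. The call of UTP13 ended on these groups alone and that of KRI1 without wild type at 37 °C replicate 3 (3.62). The total of 196 became 115 without wild type at 25 °C replicate 1, 818 and 74 without Hsf1-depleted at 25 °C replicates 2 and 1, 659, 426 and 67 without wild type at 37 °C replicates 1, 2 and 3, and 129 without Hsf1-depleted at 37 °C replicate 2.

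After 30 min at 37 °C, Hsf1-depleted cells had more called genes than wild type. HSP26 (7.72 ± 0.70), the transketolase TKL2 (9.11 ± 0.91), the hydrophilin GRE1 (8.35 ± 0.56) and HXT5 (7.68 ± 0.59) rose. DBP2 (-10.67 ± 0.57), NSR1 (-9.65 ± 0.64) and the pheromone gene MF(ALPHA)2 (-9.13 ± 0.64) fell. Among general stress genes 35 of 36 rose (35 adjusted over the list alone, median 5.38, adjusted p = 1.79e-20). For core chaperones, 10 of 18 rose and 2 fell (10 and 2 adjusted over the list alone, median 1.19, adjusted p = 0.00172, adjusted p = 0.134 with an estimated correlation). For ribosomal protein genes, 134 of 136 fell (134 adjusted over the list alone, median -4.81, adjusted p = 2.64e-49). edgeR called 1390 genes up and 1515 down (1405 and 1563 with the library set as a term). Tested as a difference from wild type, TKL2 (6.89 ± 1.13), the aldehyde dehydrogenase ALD3 (5.47 ± 0.88), HXT5 (5.30 ± 0.70), CTT1 (4.11 ± 0.60), HSP82 (2.42 ± 0.47) and KAR2 (1.98 ± 0.39) were higher, and the cell wall genes TOS6 (-7.94 ± 1.01) and SRL1 (-6.81 ± 1.15), NSR1 (-5.74 ± 0.71), RPL3 (-3.57 ± 0.39) and YDJ1 (-2.61 ± 0.27) lower (edgeR adjusted p at most 8.78e-05). Of general stress genes 21 of 36 were higher (25 adjusted over the list alone, median 1.90, adjusted p = 1.57e-12, adjusted p = 0.0892 with an estimated correlation). Among endoplasmic reticulum genes 8 of 20 were higher (9 adjusted over the list alone, median 0.84, adjusted p = 3.88e-05). For ribosomal protein genes, 128 of 136 were lower (131 adjusted over the list alone, median -3.89, adjusted p = 9.03e-90). Of core chaperones 6 of 18 were higher and 3 lower (6 and 4 adjusted over the list alone, median 0.12, adjusted p = 0.478). Higher here means a larger fold over the 25 °C level of the same state. HSP82 started from 3.069 ± 0.6989 CPM (SD) in depleted cells, against 40.8 ± 26.31 CPM in wild type. Its larger response thus does not show more HSP82 mRNA than in wild type. edgeR called 479 genes higher and 898 lower (562 and 1023 with the library set as a term).

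At 42 °C the Hsf1-depleted response differed from wild type in fewer genes than at 37 °C for 30 min. After 10 min, HSP30 (8.20 ± 0.82), CTT1 (7.41 ± 0.54), HSP26 (7.19 ± 0.69) and HSP104 (5.04 ± 0.31) rose and REI1 (-6.79 ± 0.48) fell. SSA4 was not called (0.82 ± 0.31). As differences from wild type, SSA4 (-7.53 ± 0.48), ZPR1 (-6.43 ± 0.32), BTN2 (-6.25 ± 0.61), the Hsp70 nucleotide exchange factor FES1 (-5.67 ± 0.53), the J protein APJ1 (-4.70 ± 0.35) and KAR2 (-2.59 ± 0.39) were lower, and ISA1 of iron-sulfur cluster assembly (2.15 ± 0.25) and VPS62 (2.11 ± 0.47) higher (edgeR adjusted p at most 0.00501). Among core chaperones 14 of 18 were lower (16 adjusted over the list alone, median -2.65, adjusted p = 4.05e-108). For mitochondrial chaperones, 5 of 11 were lower (5 adjusted over the list alone, median -0.28, adjusted p = 4.64e-16). Of general stress genes 2 of 36 were lower (2 adjusted over the list alone, median -0.44, adjusted p = 5.17e-05, adjusted p = 0.626 with an estimated correlation). edgeR called 1371 genes up and 1046 down (1399 and 1112 with the library set as a term) for the response. For the difference it called 4 genes higher and 64 lower (6 and 75 with the library set as a term). The call of VPS62 ended on these groups alone and without wild type at 42 °C replicate 3 (1.84). SSA4 was called in the response without the libraries that stood apart and without Hsf1-depleted at 25 °C replicate 1 (1.003).

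After 30 min at 42 °C, HSP26 (10.25 ± 0.77), the spore wall gene SPS100 (9.06 ± 0.43) and HSP82 (5.56 ± 0.39) rose in Hsf1-depleted cells, and RPS22A (-8.88 ± 0.52), the ribosome-bound Hsp70 SSB1 (-8.41 ± 0.58) and YDJ1 (-3.43 ± 0.21) fell. As differences from wild type, SSA4 (-6.86 ± 0.47), the Hsp110 SSE1 (-5.25 ± 0.30), the enolase ENO2 (-5.15 ± 0.56), YDJ1 (-4.61 ± 0.28), HSP42 (-3.90 ± 0.60) and UBI4, polyubiquitin (-2.37 ± 0.28), were lower, and VPS62 (3.11 ± 0.47) higher (edgeR adjusted p at most 8.35e-06). Of core chaperones 14 of 18 were lower (15 adjusted over the list alone, median -2.02, adjusted p = 2.30e-41). Among glycolysis genes 12 of 21 were lower (15 adjusted over the list alone, median -1.67, adjusted p = 1.74e-24). For endoplasmic reticulum genes, 6 of 20 were lower (8 adjusted over the list alone, median -0.70, adjusted p = 1.73e-09). Among mitochondrial chaperones 5 of 11 were lower (5 adjusted over the list alone, median -0.93, adjusted p = 6.77e-08). edgeR called 1808 genes up and 1651 down (1833 and 1680 with the library set as a term) for the response. For the difference it called 40 genes higher and 158 lower (98 and 266 with the library set as a term). Library totals gave 774 higher and 73 lower (91.4% higher in place of 20.2%) for the difference, and the total of 198 became 127 without Hsf1-depleted at 25 °C replicate 1.

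**Figure D2:**
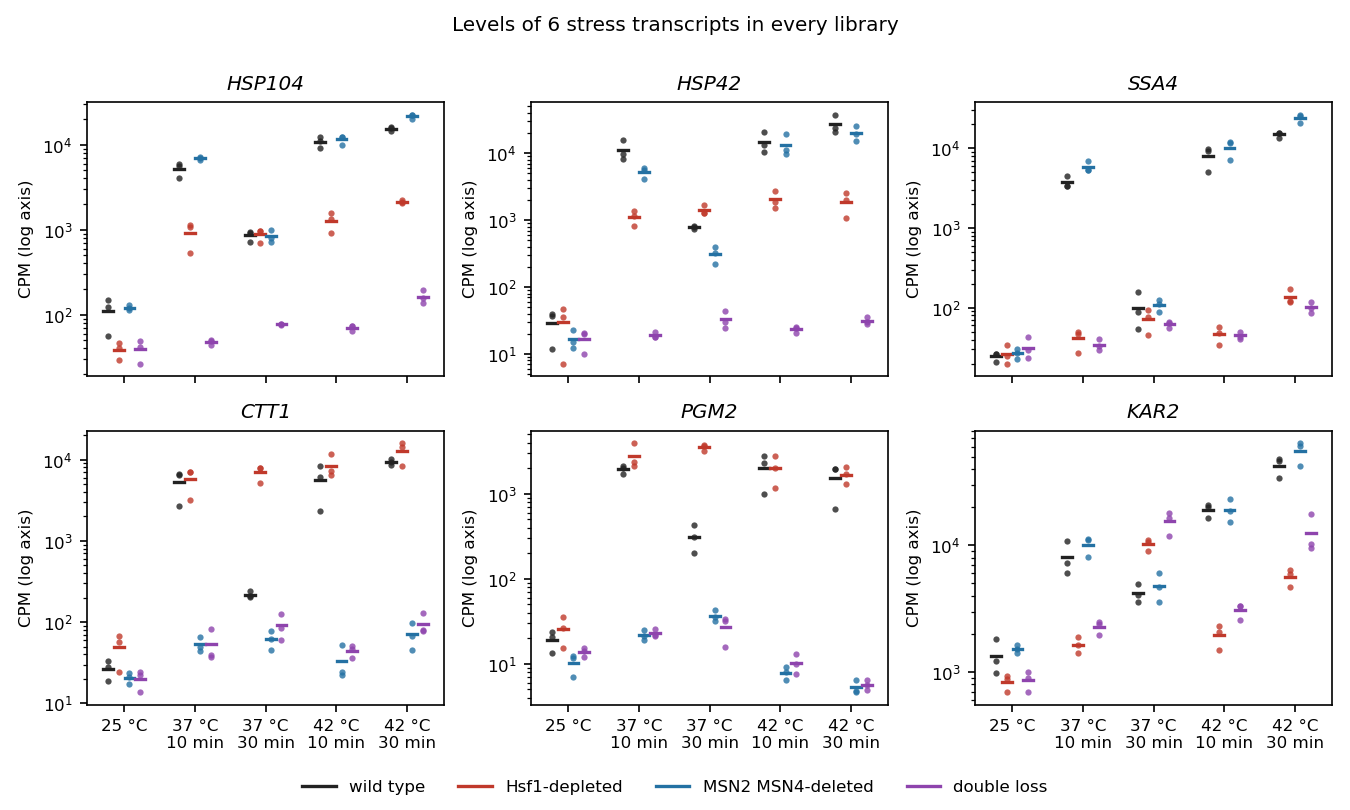
Normalised CPM on a log axis for HSP104, HSP42, SSA4, CTT1, PGM2 and KAR2 in 4 strain states and 5 conditions, with a point per library and a bar at each group mean (n = 3). At 42 °C for 30 min, the HSP42 mean was 27530 ± 8989 CPM (SD) in wild type and 31.5 ± 3.73 in the double loss.

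MSN-deleted cells at 37 °C for 10 min raised the chaperones. HSP42 (8.28 ± 0.56), SSA4 (7.75 ± 0.40), HSP104 (5.84 ± 0.32) and the mitochondrial disaggregase HSP78 (5.55 ± 0.35) rose, and NSR1 (-8.21 ± 0.59) and PUF6 (-7.22 ± 0.42) fell. For core chaperones, 18 of 18 rose (18 adjusted over the list alone, median 3.16, adjusted p = 2.38e-31). Of general stress genes 18 of 36 rose (20 adjusted over the list alone, median 1.43, adjusted p = 3.69e-08, adjusted p = 0.188 with an estimated correlation). edgeR called 487 genes up and 802 down (505 and 859 with the library set as a term). As differences from wild type, CTT1 (-6.28 ± 0.63), TSL1 (-6.18 ± 0.66), PGM2 (-5.57 ± 0.53), the phosphatase subunit GAC1 of glycogen storage (-6.40 ± 0.98) and mitochondrial superoxide dismutase SOD2 (-2.50 ± 0.52) were lower (edgeR adjusted p at most 0.000635). Among general stress genes 29 of 36 were lower (30 adjusted over the list alone, median -3.36, adjusted p = 6.68e-37). For trehalose and glycogen genes, 16 of 18 were lower (16 adjusted over the list alone, median -3.34, adjusted p = 1.35e-34). Of oxidative defence genes 1 of 30 were higher and 11 lower (1 and 11 adjusted over the list alone, median -0.73, adjusted p = 0.000165, adjusted p = 0.126 with an estimated correlation). Of core chaperones 0 of 18 were called (0 adjusted over the list alone, median -0.02, adjusted p = 0.718). edgeR called 217 genes higher and 594 lower (464 and 755 with the library set as a term). Library totals gave 615 higher and 271 lower (69.4% higher in place of 26.8%). The total of 811 became 503 without MSN-deleted at 37 °C replicate 3, 538 without MSN-deleted at 25 °C replicate 3 and 344 without wild type at 37 °C replicate 3.

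After 30 min at 37 °C in MSN-deleted cells, HSP26 (5.22 ± 0.64), HSP42 (4.21 ± 0.47) and the phosphoglycerate mutase homolog GPM2 (5.58 ± 0.69) rose and DBP2 (-6.26 ± 0.43) and the glucose transporter HXT3 (-4.69 ± 0.55) fell. edgeR called 478 genes up and 478 down (518 and 539 with the library set as a term). Library totals gave 649 up and 315 down (67.3% up in place of 50%). Few differences from wild type were called. TSL1 (-3.81 ± 0.63), PGM2 (-2.19 ± 0.51), TDH1 (-3.31 ± 0.61), SOL4 of the pentose phosphate pathway (-3.07 ± 0.61) and HPF1, a cell wall mannoprotein (-4.46 ± 0.86), were lower, and the flavohemoglobin YHB1 (2.50 ± 0.52) and GAL10 of galactose metabolism (2.48 ± 0.59) higher (edgeR adjusted p at most 0.0443). As to general stress genes, 7 of 36 were lower (14 adjusted over the list alone, median -1.25, adjusted p = 2.41e-16, adjusted p = 0.141 with an estimated correlation). Among trehalose and glycogen genes 0 of 18 were higher and 3 lower (1 and 9 adjusted over the list alone, median -1.29, adjusted p = 1.02e-12, adjusted p = 0.141 with an estimated correlation). edgeR called 2 genes higher and 14 lower (5 and 35 with the library set as a term), DESeq2 3 and 31, edgeR with DESeq2's size factors 1 and 5, no filter 1 and 8, these groups alone 19 and 81, and a fit without the libraries that stood apart 4 and 30. Each of the 12 libraries left out in turn lowered the total of 16 to between 3 and 10. The call of HPF1 ended without MSN-deleted at 37 °C replicate 1 (-4.01) or wild type at 25 °C replicate 1 (-4.13), of YHB1 without MSN-deleted at 25 °C replicates 1 (2.45) and 3 (2.51), MSN-deleted at 37 °C replicate 1 (2.32) or wild type at 37 °C replicates 2 (2.37) and 3 (2.39) and of SOL4 without MSN-deleted at 25 °C replicates 1 (-2.95) and 3 (-2.95), MSN-deleted at 37 °C replicates 1 (-2.97) and 2 (-2.95), wild type at 25 °C replicates 1 (-2.94) and 2 (-2.84) or wild type at 37 °C replicate 2 (-2.88). The call of PGM2 ended without MSN-deleted at 25 °C replicates 1 (-2.07) and 3 (-2.004), MSN-deleted at 37 °C replicates 1 (-2.13), 2 (-2.07) and 3 (-2.28), wild type at 25 °C replicates 1 (-2.32), 2 (-1.96) and 3 (-2.20) or wild type at 37 °C replicates 1 (-1.86) and 2 (-2.17), and that of GAL10 without MSN-deleted at 25 °C replicates 1 (2.31), 2 (2.64) and 3 (2.60), MSN-deleted at 37 °C replicates 1 (2.32) and 2 (2.59), wild type at 25 °C replicates 1 (2.52), 2 (2.58) and 3 (2.44) or wild type at 37 °C replicates 1 (2.71), 2 (2.23) and 3 (2.63). Both other scalings and no filter ended the calls of PGM2 and GAL10, as did DESeq2 that of GAL10.

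At 42 °C for 10 min, MSN-deleted cells raised HSP42 (9.63 ± 0.59), SSA4 (8.56 ± 0.42), BTN2 (8.26 ± 0.52) and the calmodulin-dependent kinase CMK2 (7.13 ± 0.37), and REI1 fell (-5.397 ± 0.43). CTT1 (0.67 ± 0.42), DDR2 (0.39 ± 1.04) and PGM2 (-0.39 ± 0.37) were not called. As differences from wild type, PGM2 (-7.09 ± 0.55), CTT1 (-7.06 ± 0.64), the respiratory growth gene RGI1 (-6.47 ± 0.63) and trehalose phosphatase TPS2 (-5.67 ± 0.47) were lower (edgeR adjusted p at most 1.14e-10). For general stress genes, 0 of 36 were higher and 30 lower (1 and 30 adjusted over the list alone, median -3.61, adjusted p = 2.00e-48). Of trehalose and glycogen genes 16 of 18 were lower (16 adjusted over the list alone, median -3.94, adjusted p = 2.10e-44). Among core chaperones 0 of 18 were called (0 adjusted over the list alone, median 0.02, adjusted p = 0.948). edgeR called 1185 genes up and 830 down (1192 and 906 with the library set as a term) for the response. For the difference it called 177 genes higher and 400 lower (389 and 533 with the library set as a term). For the difference, library totals gave 306 higher and 249 lower (55.1% higher in place of 30.7%) and a fit without the libraries that stood apart 638 and 737, and the total of 577 became 971 and 372 without MSN-deleted at 42 °C for 10 min replicates 1 and 2.

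At 42 °C for 30 min, MSN-deleted cells raised HSP30 (10.78 ± 0.90), HSP42 (10.22 ± 0.61), SSA4 (9.82 ± 0.44) and KAR2 (5.21 ± 0.33), and RPL3 (-5.10 ± 0.32) and the RNA polymerase I subunit RPA49 (-6.91 ± 0.49) fell. As differences from wild type, EGO4 (-8.00 ± 1.54), RGI1 (-7.69 ± 0.64), PGM2 (-7.25 ± 0.56) and CTT1 (-6.69 ± 0.64) were lower, and cytochrome b5 (CYB5 3.98 ± 0.83), the ammonium transporter MEP2 (3.26 ± 0.59) and RPL3 (1.55 ± 0.38) higher (edgeR adjusted p at most 0.00202). As to general stress genes, 27 of 36 were lower (29 adjusted over the list alone, median -3.41, adjusted p = 3.66e-33). For trehalose and glycogen genes, 17 of 18 were lower (17 adjusted over the list alone, median -3.26, adjusted p = 1.95e-29). Of oxidative defence genes 0 of 30 were higher and 15 lower (1 and 15 adjusted over the list alone, median -1.24, adjusted p = 4.21e-11). For core chaperones, 1 of 18 were higher (1 adjusted over the list alone, median 0.33, adjusted p = 0.357). Among ribosome biogenesis genes 46 of 92 were higher (52 adjusted over the list alone, median 1.57, adjusted p = 1.40e-10, adjusted p = 0.422 with an estimated correlation). edgeR called 1593 genes up and 1409 down (1605 and 1463 with the library set as a term) for the response. For the difference it called 769 genes higher and 667 lower (986 and 779 with the library set as a term). Library totals gave 1085 higher and 472 lower (69.7% higher in place of 53.6%).

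With both activities lost, heating to 37 °C for 10 min called the fewest genes of the 16 heat responses. HSP12 (3.53 ± 1.25), SSA1 (2.30 ± 0.31), KAR2 (1.40 ± 0.28) and the arginine catabolic enzyme CAR2 (3.96 ± 0.69) still rose, and DBP2 (-5.98 ± 0.42) and NSR1 (-4.85 ± 0.48) fell. HSP104 (0.29 ± 0.27) and HSP42 (0.20 ± 0.43) were not called. edgeR called 284 genes up and 519 down (341 and 533 with the library set as a term). Library totals gave 496 up and 316 down (61.1% up in place of 35.4%). The call of HSP12 ended without those libraries that stood apart, and without double loss at 25 °C replicates 1 (3.28) and 2 (2.96) or double loss at 37 °C replicate 3 (2.59). Against wild type, HSP26 (-8.67 ± 0.89), HSP42 (-8.38 ± 0.67), TSL1 (-7.40 ± 0.68) and SSA4 (-7.13 ± 0.47) were lower, and the pre-rRNA processing genes KRI1 (4.93 ± 0.88) and MTR4 (4.39 ± 0.56) higher (edgeR adjusted p at most 2.81e-05). Of core chaperones 0 of 18 were higher and 14 lower (1 and 14 adjusted over the list alone, median -2.51, adjusted p = 4.15e-20). For general stress genes, 30 of 36 were lower (31 adjusted over the list alone, median -3.88, adjusted p = 6.16e-35). Of ribosome biogenesis genes 82 of 92 were higher (88 adjusted over the list alone, median 2.87, adjusted p = 2.84e-43). edgeR called 666 genes higher and 799 lower (956 and 869 with the library set as a term). Library totals gave 1543 higher and 313 lower (83.1% higher in place of 45.5%).

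At 37 °C for 30 min in the double loss, ULI1 of the unfolded protein response (7.54 ± 0.29), TDH1 (6.42 ± 0.52), YET2 of the endoplasmic reticulum (5.27 ± 0.49) and KAR2 (4.16 ± 0.31) rose, and DBP2 (-9.71 ± 0.53), HXT3 (-7.47 ± 0.65) and RPL9A (-7.35 ± 0.45) fell. Among endoplasmic reticulum genes 18 of 20 rose (18 adjusted over the list alone, median 2.43, adjusted p = 4.98e-16). For ribosomal protein genes, 133 of 136 fell (133 adjusted over the list alone, median -4.09, adjusted p = 1.79e-61). edgeR called 1024 genes up and 1271 down (1055 and 1302 with the library set as a term). Library totals gave 1600 up and 955 down (62.6% up in place of 44.6%). Against wild type, ULI1 (6.56 ± 0.36), KAR2 (2.52 ± 0.39) and DFR1 of folate metabolism (3.36 ± 0.36) were higher, and HSP26 (-5.78 ± 0.85) and HPF1 (-7.22 ± 0.93) lower (edgeR adjusted p at most 2.15e-06). Of endoplasmic reticulum genes 14 of 20 were higher (14 adjusted over the list alone, median 1.38, adjusted p = 8.07e-10). Among ribosomal protein genes 120 of 136 were lower (121 adjusted over the list alone, median -3.005, adjusted p = 6.09e-63). For general stress genes, 15 of 36 were lower (15 adjusted over the list alone, median -1.28, adjusted p = 0.000103, adjusted p = 0.407 with an estimated correlation). edgeR called 585 genes higher and 1011 lower (777 and 1159 with the library set as a term). Library totals gave 968 higher and 593 lower (62% higher in place of 36.7%).

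At 42 °C many genes still rose in the double loss. After 10 min, CMK2 (6.71 ± 0.36), MNC1 (6.65 ± 0.55), proline oxidase PUT1 (6.13 ± 0.41) and RTA1, a membrane protein of the lipid-translocating family (5.89 ± 0.44), rose and REI1 (-4.82 ± 0.41) fell. After 30 min, RTA1 (8.34 ± 0.48), MNC1 (8.08 ± 0.58), CMK2 (7.84 ± 0.38), HSP82 (4.58 ± 0.37), KAR2 (3.86 ± 0.31) and HSP104 (2.06 ± 0.27) rose and RPL9A (-6.71 ± 0.42) fell (edgeR adjusted p at most 8.74e-09). Of the genes that rose in wild type, 776 of 1405 (55.2%) at 10 min and 1159 of 1832 (63.3%) at 30 min were also called up here, against 213 of 1274 (16.7%) and 370 of 874 (42.3%) at 37 °C. At 42 °C for 30 min, of endoplasmic reticulum genes 14 of 20 rose and 1 fell (14 and 1 adjusted over the list alone, median 1.74, adjusted p = 3.17e-05). Among core chaperones 9 of 18 rose and 1 fell (9 and 1 adjusted over the list alone, median 1.12, adjusted p = 0.0325, adjusted p = 0.288 with an estimated correlation). Of ribosomal protein genes 132 of 136 fell (132 adjusted over the list alone, median -4.53, adjusted p = 3.56e-46). edgeR called 1039 genes up and 823 down (1089 and 828 with the library set as a term) at 10 min and 1547 genes up and 1492 down (1599 and 1488 with the library set as a term) at 30 min. There library totals gave 1264 up and 508 down (71.3% up in place of 55.8%) and 2023 up and 1025 down (66.4% up in place of 50.9%).

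**Figure D3:**
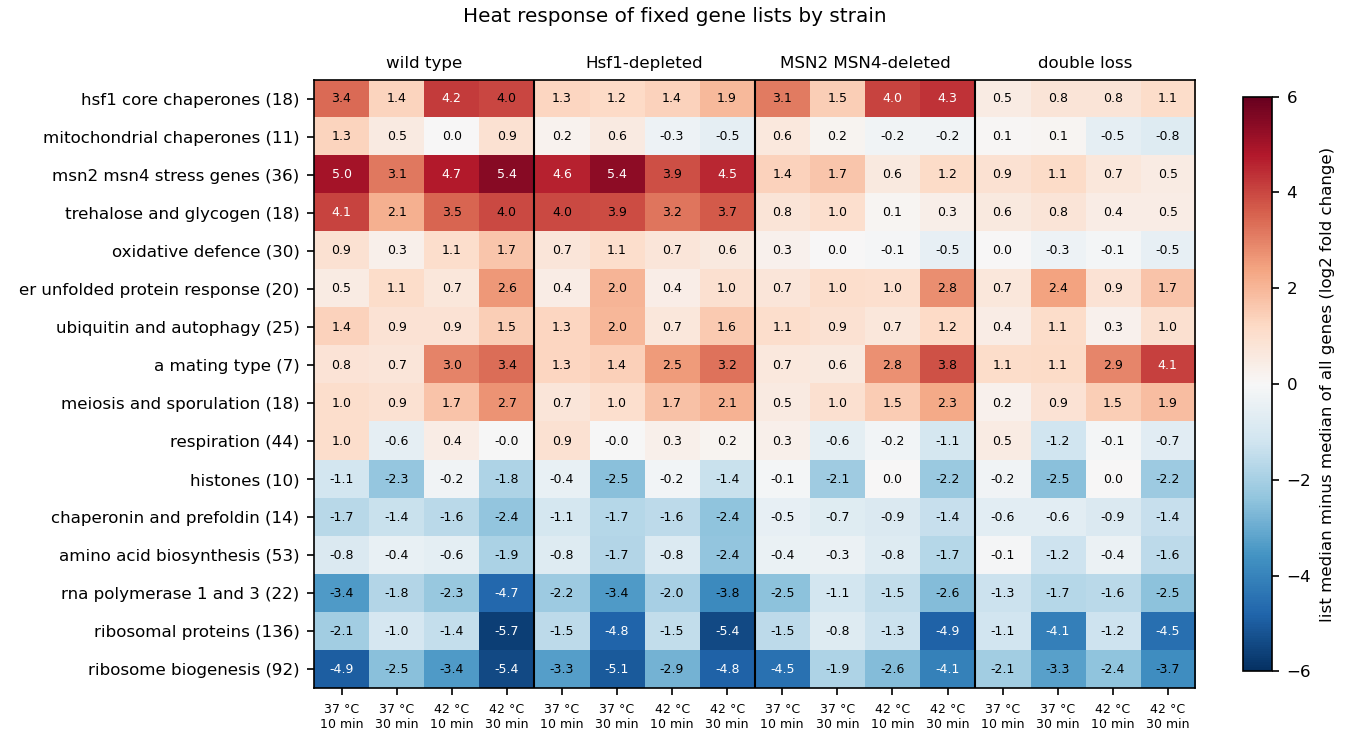
Each cell of the heat map gives, for 1 of 16 gene lists (down) and 1 of 16 strain states and heat conditions (across), the median log2 fold change of the list against 25 °C minus the median of all tested genes, on a linear colour scale. In wild type at 42 °C for 30 min the unshifted medians were 3.95 for core chaperones and -5.71 for ribosomal protein genes, and in the double loss 1.12 and -4.53.

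Against wild type at 42 °C for 10 min, the double loss had lower HSP42 (-8.48 ± 0.67), HSP30 (-8.59 ± 1.03), SSA4 (-7.85 ± 0.48) and PGM2 (-7.13 ± 0.55) and higher ISA1 (2.53 ± 0.25) and CYB5 (2.71 ± 0.80). After 30 min, HSP42 (-8.96 ± 0.67), DDR2, a small stress-induced protein (-8.60 ± 1.25), HSP26 (-7.74 ± 0.86) and SSA4 (-7.57 ± 0.48) were lower, and YHB1 (4.04 ± 0.53), CYB5 (3.96 ± 0.82) and RPL3 (1.78 ± 0.38) higher (edgeR adjusted p at most 0.000277). At 10 and 30 min in turn, of core chaperones 14 of 18 were lower (15 adjusted over the list alone, median -3.29, adjusted p = 1.04e-46) and 16 of 18 were lower (16 adjusted over the list alone, median -3.05, adjusted p = 1.95e-22). Among general stress genes 30 of 36 were lower (32 adjusted over the list alone, median -3.61, adjusted p = 1.89e-47) and 32 of 36 were lower (32 adjusted over the list alone, median -4.29, adjusted p = 1.38e-33). For trehalose and glycogen genes, 17 of 18 were lower (17 adjusted over the list alone, median -3.53, adjusted p = 1.57e-21) at 30 min. edgeR called 155 genes higher and 481 lower (271 and 569 with the library set as a term) at 10 min and 1041 genes higher and 903 lower (1305 and 986 with the library set as a term) at 30 min. Library totals gave 960 higher and 239 lower (80.1% higher in place of 24.4%) and 2717 higher and 362 lower (88.2% higher in place of 53.5%), with 25 called genes changing sign at 30 min, and a fit without the libraries that stood apart called 478 and 765 at 10 min. The call of CYB5 at 10 min ended without double loss at 25 °C replicates 1 (2.38) and 3 (2.48) or wild type at 42 °C replicates 2 (2.35) and 3 (2.55).

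The non-additivity test asks whether losing both activities changes a heat response by more or less than the sum of the single losses. HSP104 (YLL026W, chromosome XII, 88623 to 91349), HSP42 (YDR171W, chromosome IV, 806621 to 807748) and HSP78 (YDR258C, chromosome IV, 971808 to 974243) were lower than additive at each of the 4 heat conditions. HSP42 had -4.71 ± 0.85 and -4.07 ± 0.84 after 10 and 30 min at 37 °C, and -6.26 ± 0.85 and -5.41 ± 0.85 at 42 °C. HSP104 had -4.54 ± 0.53, -3.36 ± 0.53, -4.15 ± 0.53 and -4.10 ± 0.53, and HSP78 -3.65 ± 0.60, -2.21 ± 0.59, -3.62 ± 0.60 and -3.33 ± 0.59, in the same order. UBI4 (-2.18 ± 0.39) at 37 °C for 10 min and the recombination gene CSM2 (-2.93 ± 0.54) at 42 °C for 30 min were lower too. At 37 °C for 30 min, TKL2 (-6.88 ± 1.603), HXT5 (-5.53 ± 0.96) and HXK1 (-5.52 ± 0.93) were lower and TOS6 (4.79 ± 1.29), the polyamine transporter TPO2 (4.12 ± 0.99) and ULI1 (3.82 ± 0.49) higher (edgeR adjusted p at most 0.0253). Of core chaperones at 42 °C for 30 min 3 of 18 were lower (3 adjusted over the list alone, median -1.07, adjusted p = 3.28e-13), and of general stress genes at 37 °C for 30 min 11 of 36 were lower (24 adjusted over the list alone, median -2.20, adjusted p = 6.50e-24). edgeR called 0 genes higher and 4 lower (1 and 4 with the library set as a term), 70 genes higher and 110 lower (172 and 202 with the library set as a term), 0 genes higher and 3 lower (0 and 4 with the library set as a term) and 0 genes higher and 4 lower (0 and 4 with the library set as a term) over the 4 conditions. Against the 0 genes higher at 37 °C for 10 min and at 42 °C, 499, 141 and 138 genes had an unadjusted p under 0.05 and DESeq2 called 4 and 7, 0 and 4, and 0 and 4. Library totals gave 88 higher and 91 lower (49.2% higher in place of 38.9%) at 37 °C for 30 min, and fits on these groups alone called 0 and 1 at 37 °C for 10 min and at 42 °C for 30 min. Such fits ended the calls of HSP78 at each condition, of UBI4 and CSM2 and, at these 2 conditions, of HSP42, while HSP104 stayed called in each of the 4. The call of HSP78 at 37 °C for 30 min also ended under library totals, without the libraries that stood apart and without Hsf1-depleted at 25 °C replicate 2 (-2.09), double loss at 25 °C replicate 2 (-1.79), MSN-deleted at 25 °C replicate 2 (-2.16), wild type at 25 °C replicate 3 (-2.01) or wild type at 37 °C replicate 1 (-2.14), and that of TOS6 without Hsf1-depleted at 25 °C replicate 1 (3.94), double loss at 25 °C replicate 2 (4.23), double loss at 37 °C replicate 3 (3.66), MSN-deleted at 37 °C replicate 1 (4.34), wild type at 25 °C replicate 3 (4.55) or wild type at 37 °C replicate 1 (4.52).

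Of the genes that rose in wild type, more responded less after MSN deletion than after Hsf1 depletion at 3 of the 4 conditions. At 37 °C for 10 min, 526 of 1274 were lower with MSN2 and MSN4 deleted and 77 with Hsf1 depleted, and at 42 °C for 10 and 30 min 334 and 61 of 1405 and 487 and 98 of 1832. At 37 °C for 30 min the main fit gave 14 and 40 of 874, while the libraries of these groups alone gave the other order, 70 and 43 of 808. DESeq2 gave 28 and 38, a term for library sets 28 and 58, a fit without the libraries that stood apart 28 and 41, edgeR with DESeq2's size factors 5 and 35, no filter 8 and 36, and an adjusted p under 0.01 gave 5 and 26. Each of the 12 MSN-deleted and wild-type libraries at 25 °C and at 37 °C for 30 min left out in turn lowered the 14 to between 3 and 8, and the 40 became 24 without wild type at 25 °C replicate 3. Genes lower in both single losses numbered 28, 1, 4 and 10 over 37 °C for 10 and 30 min and 42 °C for 10 and 30 min, against 31.8, 0.641, 14.5 and 26.1 for independent draws. A further 205, 234, 71 and 151 were called lower in the double loss and in neither single loss. In 5 simulations of unchanged strains, at 1 of the 4 conditions, 0 rises were called lower. This cannot test the overlap, nor chance, since some exchanges of library labels called genes (below).

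The authors' table covers the 16 heat responses. At the same thresholds on its values, 1283 genes were up and 1260 down in wild type at 37 °C for 10 min, 1212 and 1239 of them shared with the edgeR calls, and 1900 and 1713 at 42 °C for 30 min, with 1798 and 1690 shared. In the 16 responses 0 genes were called up in that table and down here or the reverse. Across genes, which are not independent replicates, the correlation of the fold changes was 0.995 to 0.999. The table holds no strain differences used here.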

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

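Of the tests below, those of scaling, library set, single libraries, mislabelling, rapamycin, slower return and residual Hsf1, and the exchanges of labels for Hsf1 depletion at 42 °C for 10 min and non-additivity at 37 °C for 10 min, were chosen only after the result was seen, as were the look at which exchanges keep whole groups and the exchanges within library sets. Each result here is a tested difference between groups.

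Differences of heat response from wild type were called for 196, 1377, 68 and 198 genes with Hsf1 depleted, 811, 16, 577 and 1436 with MSN2 and MSN4 deleted and 1465, 1596, 636 and 1944 with both lost (37 °C for 10 and 30 min, then 42 °C for 10 and 30 min, here and below). Library sets as a term gave 633, 1585, 81 and 364 genes, then 1219, 40, 922 and 1765, then 1825, 1936, 840 and 2291. Non-additivity was called for 4, 180, 3 and 4 genes (5, 374, 4 and 4 with the set term). Within wild type, 1337 and 2660 genes differed between temperatures at 10 and 30 min, and 1142 and 1629 between times at 37 °C and 42 °C. Genes called up in wild type and down in another state, or the reverse, numbered 4, 12, 6 and 15 with Hsf1 depleted, 7, 1, 12 and 35 with MSN2 and MSN4 deleted, and 7, 63, 13 and 71 with both lost.

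Strain labels of the 12 libraries of each difference were exchanged within conditions in 100 draws, the real one included, and fitted on those libraries alone. For Hsf1 depletion, 4, 7, 16 and 1 of 100 gave as many genes as the real 35, 1378, 49 and 144, and the highest others were 298, 1833, 755 and 137. For MSN deletion, 5, 8, 4 and 3 of 100 did (real 822, 100, 585 and 1754, highest others 1220, 475, 748 and 1876), and for both losses 5, 7, 5 and 4 (real 991, 1208, 547 and 1856, highest others 2300, 2414, 835 and 2727). For non-additivity, with 24 libraries, 3, 7, 2 and 3 did (real 1, 190, 2 and 1, highest others 159, 940, 1361 and 803). These shares were under 5% for Hsf1 depletion at 37 °C for 10 min and 42 °C for 30 min. The same held for MSN deletion at 42 °C and both losses at 42 °C for 30 min, and not for the other 7 differences. Draws that keep or exchange the 3 libraries of each group together in a condition still hold that condition's strain difference, so they can call as many genes without chance being the cause. Without them, 1 of 79 and 1 of 83 draws, the real ones, were as large for Hsf1 depletion at 37 °C and at 42 °C for 30 min, 1 of 86, 82, 78 and 81 for MSN deletion and 1 of 79, 82, 86 and 80 for both losses. The highest other draw then called 0 genes in each of these 10. This speaks against chance, but was looked at only after the shares were known, and leaves it open. For Hsf1 depletion after 10 min, 2 of 85 draws at 37 °C and 4 of 82 at 42 °C were as large. The others of these called 298 genes at 37 °C and 356 to 755 at 42 °C, so chance stays open at both. The 3 draws at 42 °C shared 1 split of the heated libraries (wild type replicates 1 and 2 with Hsf1-depleted replicate 3 against the others), which points to a structure other than strain among these 6, of untested cause. Exchanged within library sets, Hsf1 depletion has 19 arrangements without whole groups, the real one included, too few for a share under 0.05, and the highest other called 0 genes at each condition. For non-additivity chance is not excluded at 37 °C for 30 min, and real counts of 1, 2 and 1 genes are too small to read. Draws of 159 to 1361 genes against such counts may reflect a structure of the samples, which was not tested. Library residuals had a mean correlation of 0.28 within sets and -0.14 between sets of the same MSN background. The 100 draws ignore this, so no share excludes chance.

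At 37 °C for 30 min, Hsf1-depleted cells responded more than wild type in 128 of 136 ribosomal protein genes, which were lower (adjusted p = 0.0001388 by camera with an estimated correlation). Of general stress genes 21 of 36 were higher, but the list lost its call with an estimated correlation (camera adjusted p = 0.0892). Against the choice of scaling, the other scalings still called at least 1230 genes. Against the library set its term left 1585, and against a single library leaving out any 1 left at least 1245. Against 37 °C libraries having been heated to 42 °C, 1977 genes were called between the 42 °C and 37 °C groups of the depleted state at 30 min. Rapamycin acting by itself cannot be told apart, since each depleted library and no other had it, although 0 of 253 members of the ribosome and nitrogen lists were called at 25 °C. Against a slower return of ribosomal protein genes from their level at 10 min, 128 of 136 were lower at 30 than at 10 min in depleted cells (median -3.28, quartiles -3.72 and -2.59, log2), while 71 were higher in wild type. A longer fall before any return and 30 min of added depletion stay open. So does a slower return of general stress genes, of which 8 of 36 were higher and 3 lower at 30 than at 10 min.

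HSP104, HSP42 and HSP78 rose in each single loss and less in the double loss, by little for HSP78 at 37 °C for 30 min (2.16 ± 0.31 in the double loss and 2.60 ± 0.31 in MSN-deleted cells). Against scaling, the non-additivity kept a size of at least 2.19 (log2) over the 3 genes, the 4 heat conditions and the other scalings. Against leftover Hsf1 as the only source of the rise in depleted cells, MSN deletion would then add nothing, yet the non-additivity nearest to 0 was -2.206, for HSP78 at 37 °C for 30 min, where leaving out any 1 of 5 libraries ended its call. A candidate explanation is that Hsf1 and Msn2 or Msn4 can each drive these genes, since they hold a mean of 3 AGGGG sites (the Msn2 and Msn4 motif) in the 500 bp upstream against 0.467 in the other 15 core genes (exact permutation, two-sided p = 0.00123, the smallest that 816 arrangements can give). This is a hypothesis found on the same data, and fits on the compared groups alone ended the call of HSP78 at each condition and that of HSP42 at 2 of them.

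At 42 °C, 1039 genes rose after 10 min and 1547 after 30 min in the double loss. Against scaling, the other scalings still called at least 1650 rises at 30 min. Against leftover Hsf1 at 10 min, depletion alone changed the 1039 responses by a median of 0.01 (log2, quartiles -0.319 and 0.344, 17 lower). The core list changed by -2.649. Picking genes that rise with Hsf1 depleted weakens this. Against loss of ribosomal mRNAs from the libraries, 1497 of the other genes rose with ribosomal genes taken out, and 1546 with them. At 10 and at 30 min leftover Hsf1, a further heat-activated regulator or slower mRNA decay stays open, the last 2 untested.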

How the results depend on the processing

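The fit without 5 libraries that stood apart (MSN-deleted at 42 °C for 10 min replicate 1, double loss at 25 °C and 37 °C for 30 min replicate 2, Hsf1-depleted at 25 °C replicate 1 and wild type at 37 °C for 10 min replicate 3) was chosen after seeing the data, and the other alternatives before. No list or named gene turned its direction, and library totals changed the sign of 25 genes called for the double-loss difference at 42 °C for 30 min. Of 255 pairs of a named gene and a comparison, 29 changed their call, 19 on leaving out 1 library and 25 in another setting, and the report names the libraries and the settings other than the stricter p. Where counts moved by over 1.5 times, the cause was not tested, except that an adjusted p under 0.01 calls fewer genes by construction. Depth limits folds of genes under 0.78 CPM.

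With Hsf1 depleted, the difference from wild type at 37 °C for 10 min (196 genes) was 472 with DESeq2, 633 with library sets, 35 on the compared libraries alone, 54 without those that stood apart, 71 at an adjusted p under 0.01 and 67 to 818 leaving out 1 library. At 42 °C for 30 min (198) it was 364 with library sets, 847 under library totals, 123 at the stricter p and 127 to 293 leaving out 1 library. With MSN2 and MSN4 deleted, the difference at 37 °C for 10 min (811) was 1219 with library sets, 390 at the stricter p and 344 to 1091 leaving out 1 library. At 37 °C for 30 min (16) it was 34 with DESeq2, 6 with DESeq2's size factors, 9 without the filter, 100 on the compared libraries alone, 40 with library sets, 34 without those that stood apart, 5 at the stricter p and 3 to 10 leaving out 1 library. At 42 °C for 10 min (577) it was 922 with library sets, 1375 without those that stood apart, 329 at the stricter p and 372 to 971 leaving out 1 library, and at 42 °C for 30 min (1436) 919 at the stricter p.

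With both lost, the difference at 42 °C for 10 min (636) was 1199 under library totals, 1243 without the libraries that stood apart and 398 at the stricter p, and at 42 °C for 30 min (1944) 3079 under library totals. Non-additivity was 11 with DESeq2 and 1 on the compared libraries at 37 °C for 10 min (4), 374 with library sets and 80 at the stricter p at 37 °C for 30 min (180), and 1 on the compared libraries at 42 °C for 30 min (4). At 25 °C, MSN deletion (7) gave 14 with DESeq2 and 12 without those that stood apart, the double loss (30) 12 on the compared libraries and 50 without those that stood apart, and against MSN-deleted cells (20) 9 on the compared libraries.

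With replicate number as a block, MSN deletion gave 11 genes at 25 °C and 25 for the difference at 37 °C for 30 min. Of 40 counts, 38 stayed within 1.5 times. Libraries with the same replicate number had a mean correlation of their residuals of 0.036 (-0.88 to 0.91), so the numbers were not taken to pair samples. Libraries of the same set, which holds 1 library of each of 10 groups, had 0.28, against -0.14 for other sets of the same MSN background, and 44 of 60 were closest to their own set. The set thus links samples across conditions, and the fits with it as a term allow for this.

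Of 1080 list tests, 397 lost their call with an estimated correlation, and 10, 38 and 4 under DESeq2's size factors, library totals and the replicate block, with 11 of 1026 under library sets. Calls were gained in 3, 22, 4 and 5 tests in the same order. No filter moved 1 of 40 counts.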

Other observations

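Of the tests here, the split of libraries for wild type at 42 °C for 10 min was chosen only after the result was seen. The motif tests were stated before their result was seen, and the lists for mating type and meiosis were fixed before the data were examined.

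Genes of the a mating type rose at 42 °C for 30 min in each strain state. Of 7 such genes, 6 of 7 rose (6 adjusted over the list alone, median 3.33, adjusted p = 0.00161) in wild type, 7 of 7 rose (7 adjusted over the list alone, median 3.25, adjusted p = 0.00246) in Hsf1-depleted, 7 of 7 rose (7 adjusted over the list alone, median 3.88, adjusted p = 4.87e-05) in MSN-deleted and 7 of 7 rose (7 adjusted over the list alone, median 4.12, adjusted p = 6.79e-05) in double-loss cells. The alpha genes fell in wild type (5 of 5 fell (5 adjusted over the list alone, median -3.76, adjusted p = 0.00226, adjusted p = 0.0922 with an estimated correlation)) and in the double loss (5 of 5 fell (5 adjusted over the list alone, median -4.16, adjusted p = 0.000235, adjusted p = 0.0703 with an estimated correlation)). Of meiosis and sporulation genes, 13 of 18 rose (13 adjusted over the list alone, median 2.67, adjusted p = 0.000153) in wild type and 15 of 18 rose (15 adjusted over the list alone, median 1.87, adjusted p = 7.51e-05, adjusted p = 0.0515 with an estimated correlation) in the double loss.

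Genes whose wild-type rise at 42 °C for 10 min was lower in MSN-deleted or Hsf1-depleted cells were searched for the motif of each factor in the 500 bp upstream, among the 1194 of 1405 risen genes (85.0%) that matched the reference and had 500 bp before their start, which may reach into neighbouring genes. At least 2 AGGGG sites stood before 136 of 327 Msn2/4-dependent genes (41.6%) and 130 of 867 others (15.0%, odds ratio 4.04, Fisher's exact p = 3.29e-21, two-sided). A heat shock element of 3 units stood before 19 of 59 Hsf1-dependent genes (32.2%) and 20 of 1135 others (1.76%, odds ratio 26.5, Fisher's exact p = 2.4e-16). The crossed pairings gave 20.3% against 22.4% for AGGGG sites at Hsf1-dependent genes (Fisher's exact p = 0.873) and 2.14% against 3.69% for heat shock elements at Msn2/4-dependent genes (Fisher's exact p = 0.205). These values are consistent with direct action of each factor on part of its dependent genes, as a hypothesis, since binding was not measured. HSP104 holds AGGGG sites 252, 220 and 172 bp before its start and overlapping elements TTCCAGAATTTTC and GAATTTTCTAGAA at 302 and 297 bp. HSP42 holds sites at 212, 200 and 182 bp and elements TTCTGGAAGGTTC and GAAGGTTCGCGAA at 243 and 238 bp, and HSP78 sites at 196, 164 and 130 bp and elements TTCCAGAATGTTC and GAATGTTCTAGAA at 247 and 242 bp. The mean number of elements was 2 in these 3 genes and 0.867 in the other 15 core genes (exact permutation p = 0.162).

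For comparisons of 2 groups, 6 libraries make 10 splits, too few for a share under 0.05. On the 6 libraries alone, the real split called 559 to 3395 genes in the 16 heat responses and 963 to 2514 in the 4 comparisons within wild type, against 0 in any other split, and 1 of 10 was as large. At 25 °C the real split called 8, 7, 12 and 9 genes for Hsf1 depletion, MSN deletion, double loss against wild type and double loss against MSN-deleted cells, and the highest other 0, 1, 0 and 0.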
